A study of Mus musculus with 2 samples.

How the data were processed

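Total RNA of pooled CX3CR1high CD11b+ CD11c+ cells of the colon lamina propria and of pooled blood Ly6c+ CD11b+ monocytes was labelled from 25 ng each and hybridised to 2 Agilent whole mouse genome arrays of 60-base probes (design 026655), per the labels' protocols and the file headers. On array 1 the colon pool carried Cy5 and the blood pool Cy3, and on array 2 the dyes were swapped, per the labels. The labelling amplified RNA from an oligo-dT primer, per the labels' protocols. Both arrays lay on 1 slide and shared 1 scan time, so no batch could be tested. Whether both arrays used the same extracts is not stated in so many words. They were counted as 1 replicate because both name the same pools.

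The deposited scanner files give the mean intensity of each spot and the median intensity of its surroundings in both channels, in linear units without normalization, per the file headers. They also give the software's log10 ratio of red over green, after its own detrending and dye normalization, per the file headers. Agilent Feature Extraction is given as version 10.7.3.1 in the file headers and as 10.5.1.1 in the submitters' processing notes. The deposited value table of the series holds log10 ratios. Matched by spot number, it equals the scanner software's log10 ratio on array 1 and that ratio with its sign turned on array 2, with a largest difference of 4.81e-08, so its scale and its direction, colon over blood, are settled. Its centring is that of the software, the median of both columns is 0, and 8608 and 8862 spots are at exactly 0.

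Each array has 44397 spots, of which 43020 are not controls. Intensities were corrected with the normexp method and an offset of 50, fitted on all spots, and each array was normalized by loess with control and outlier spots at weight 0 (limma 3.58.1 in R 4.3.3). Spots of one probe were averaged after outlier spots were left out, which left 39424 probes. Spots were named through RefSeq accessions for 29529, by the name in the file for 8751, and not at all for 4740, with gene names of assembly GRCm38 used for names alone. Probe positions are those of the files, on mouse build mm9. Of several probes of a gene, the one of highest mean intensity gave its value. Among 3655 genes with 2 or more measured probes, 1 had probes at least 2-fold higher and at least 2-fold lower. The ratio of array 2 was turned before averaging, so a dye effect common to both arrays cancels in the mean. A gene was measured when the same pool was well above background on both arrays, by the flag of the scanner software. The median mean intensity was 62.2 (blood pool, Cy3) and 89.5 (colon pool, Cy5) on array 1, and 64.8 (colon pool, Cy3) and 74.5 (blood pool, Cy5) on array 2, over a local background of 40.5 to 43. The offset therefore compresses the ratios of dim genes. No spot was saturated.

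With 1 replicate there was no test, and genes were called by size: a log2 ratio of at least 1 or at most -1 on each array, with the brighter pool well above background on both. SDs are over the 2 arrays. Genes not well above background in 1 pool on both arrays, over all their probes, were given a bound, computed as the bright pool's mean normalized log2 signal minus, per array, the higher of the lowest signal among probes well above background in that channel and the dim probe's own, after loess and Aquantile. Before the data were examined, 39 gene lists with 805 members were fixed, of which 798 had a named probe. For each list the members past the size rule were counted, and its median was placed among 10000 random lists matched in 20 bins of mean intensity, as a description and not a p-value. The rule for named genes, fixed at the same time, took the sort genes, the 12 highest and 12 lowest genes well above background and unsaturated in both pools, the 6 largest bounds per direction, and up to 4 list members per direction, or the 2 brightest members where none passed. Further lists were added after the data were seen and are named as such where they appear.

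Alternatives fixed before the data were examined were no background correction, an offset of 16, median centring, the software's ratios, the deposited value table, Aquantile scaling, the mean over probes, each array alone, no filter or a filter on both pools, other fold thresholds, random lists not matched on intensity, and lists without shared members. The method was tested on simulated arrays of 43020 probes made from the real intensities. For the simulated comparison of the colon pool against the blood pool, 100 of 100 probes changed by 1.5 on the log2 scale and 100 of 100 changed by 3 were called, with fitted sizes of 1.41 and 2.81 in the median and 0 calls among unchanged probes. The changed probes were few, were drawn from bright spots alone and were balanced in direction. The simulation therefore tests neither dim genes nor the loess fit where many genes change mostly in 1 direction. Of 100 simulated unchanged gene lists over 15678 genes, 5 lay outside percentiles 2.5 to 97.5. The ratios were permuted over genes and these lists drawn at random, so a count near this one follows by construction. It checks the ranking step and not lists of genes that vary together. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used. Left out were control spots, outlier spots, unnamed probes from gene counts, 11560 of 27238 genes by the filter on dim probes, and all but 1 probe of each gene from its value.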

Results

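Gene expression was compared between 2 pools of sorted mouse cells. The first pool held CX3CR1high CD11b+ CD11c+ cells from the lamina propria, the connective tissue under the epithelium, of the large intestine of CX3CR1gfp/+ mice, in which 1 allele of the fractalkine receptor gene Cx3cr1 is replaced by green fluorescent protein. The second pool held Ly6c+ CD11b+ monocytes from the blood of C57BL/6J mice. They are called the colon pool and the blood pool here. The design text gives n = 10 for the colon cells and n = 6 for the blood cells without saying what n counts. Both pools were hybridised together on 2 two-colour arrays with the dyes swapped, so the 2 arrays measure the same 2 pools and count as 1 replicate. No p-value was computed. Every value below is a log2 ratio of the colon pool over the blood pool, averaged over both arrays, with the SD between the arrays, which covers technical error alone. Between 52.9% and 59.6% of the probe spots were well above background in each pool and dye, and 15678 genes were measured. The number of arrays limits the precision, and tissue, mouse strain and isolation procedure differed together with the cell type.

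A gene was called different when its ratio was at least 2-fold in the same direction on each array. By this rule 2224 genes were higher and 699 were lower in the colon pool, which together are 18.6% of the measured genes. Differences of at least 8-fold on both arrays were seen for 448 higher and 31 lower genes. Among genes well above background in both pools, the highest ratio belonged to Adamdec1, a metalloprotease-like gene of the resident intestinal macrophage list (7.43 ± 0.03, 172-fold). Next were Ifnb1, which encodes interferon beta (7.19 ± 0.37), and Dcn, the matrix proteoglycan decorin (7.01 ± 0.08). The chemokine genes Ccl7 (7.01 ± 0.07), Cxcl1 (6.96 ± 0.17), Ccl8 (6.90 ± 0.03) and Ccl4 (6.44 ± 0.02), the membrane protein gene Ms4a7 (6.97 ± 0.15), the collagenase gene Mmp13 (6.67 ± 0.21) and the collagen genes Col1a1 (6.79 ± 0.04), Col3a1 (6.75 ± 0.16) and Col1a2 (6.37 ± 0.05) followed. The second Adamdec1 probe read 3.62. The lowest ratios belonged to Chil3, a chitinase-like secreted protein (-6.98 ± 0.19, 126-fold lower), LOC620515 (-6.08 ± 0.17), the neutrophil collagenase gene Mmp8 (-4.99 ± 0.30), Serpinb10 (-4.68 ± 0.21) and Plac8 (-4.55 ± 0.12). Gm9733 (-4.54 ± 0.02), Ifitm6 (-4.37 ± 0.03), I830127L07Rik (-4.35 ± 0.24), the transcription factor gene Nfe2 (-4.19 ± 0.15), the haptoglobin gene Hp (-4.04 ± 0.38) and Gpr141 (-3.99 ± 0.59) were also among the 12 lowest. Across genes the ratios of both arrays correlated with Pearson's r = 0.968 and Spearman's rho = 0.921, although genes are not independent replicates. Of all calls, 76.1% were higher in the colon pool. With the ratios of the scanner software 3175 genes were higher and 2081 lower (60.4% higher), and with median centring in place of the loess fit 1137 were higher and 558 lower (67.1% higher). The median of all measured genes was 0.06, and became -0.12 and -0.28 under these scalings.

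**Figure D1:**
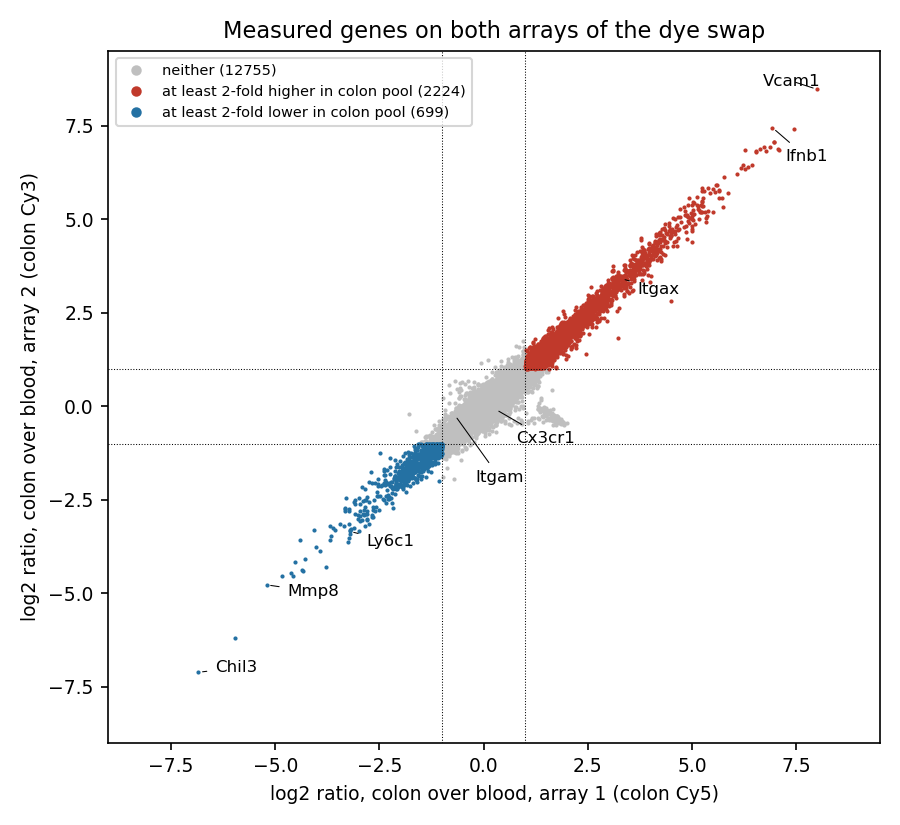
Log2 ratio of the colon pool over the blood pool for each of the 15678 measured genes, on array 1 (horizontal axis, colon pool in Cy5) and array 2 (vertical axis, colon pool in Cy3), with dotted lines at 2-fold. The 2224 higher genes (red) and 699 lower genes (blue) lie along the diagonal, from Chil3 at -6.98 to Vcam1 at 8.23 in the mean of both arrays.

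The genes whose products defined the sorts were read first. Itgax, which encodes CD11c (probe on chromosome 7, 135294052 to 135294111, mouse build mm9), was higher in the colon pool at 3.35 ± 0.08 (10.2-fold). Ly6c1 (chromosome 15, 74875495 to 74875554) was lower at -3.28 ± 0.09, and its other probe read -3.65. A probe named Ly6c2 was not used here, and related Ly6 transcripts may share signal with the Ly6c1 probes. Itgam, which encodes CD11b (chromosome 7, 135260275 to 135260334), a marker of both sorts, did not pass at -0.46 ± 0.33, with -0.35 and 0.13 from its other probes and values from -1.19 (median centring) to -0.23 under the alternatives tried. Cx3cr1 (chromosome 9, 119957811 to 119957870) did not pass either, at 0.10 ± 0.25, with 0.16 from its other probe. Its values ran from -0.69 to 0.28 under the alternatives tried. In the mice of the colon pool an allele of Cx3cr1 was replaced by green fluorescent protein, which is not stated for those of the blood pool. The Cx3cr1 ratio therefore cannot separate gene dose from expression per allele, and equal expression cannot be read from it.

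Extreme percentiles were common among the gene lists. Of the 39 lists, 23 lay at or above the upper percentile limit named in the methods and 6 at or below the lower one. The random lists were matched on intensity and not on how genes vary together. An extreme percentile alone therefore does not set a list apart from the others. Of the 30 measured members of the list of resident intestinal macrophage genes, 23 were higher in the colon pool and 0 lower, with a median of 3.05 that lay at percentile 100 of 10000 random lists of matched intensity. Apart from Adamdec1, the highest were Dab2, an endocytic adaptor (6.66 ± 0.20, with a blood signal well above background on 1 array alone), Mrc1, the mannose receptor CD206 (5.78 ± 0.12), and C1qb (5.70 ± 0.07). Other lists hold 20 of the 30 members, and without them the median was 3.07. In the list of Ly6C-high monocyte genes the direction was opposite. There 20 of 24 members were lower in the colon pool and 0 higher, with a median of -3.13 at percentile 0. After Chil3, the lowest were Mmp8, Plac8 and Ifitm6. Of 11 genes of Ly6C-low monocytes, 7 were lower and 2 higher, with a median of -1.55 at percentile 0. The leukosialin gene Spn (-2.99 ± 0.09), Ace (-1.90 ± 0.01), Itgal (-1.85 ± 0.02) and Eno3 (-1.63 ± 0.25) were lower, whereas the lipid scavenger receptor gene Cd36 (3.26 ± 0.07) and Fabp4 (1.096 ± 0.00) were higher, although Fabp4 lost its call under median centring (0.53).

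Genes of antigen presentation by MHC class II were higher in the colon pool for 13 of 17 members and lower for 0, with a median of 2.67 (percentile 100). Examples are the costimulatory genes Cd83 (4.98 ± 0.14) and Cd86 (3.58 ± 0.09), the class II chain gene H2-Aa (4.51 ± 0.15) and the invariant chain gene Cd74 (3.88 ± 0.14). Genes of the IL-10 and TGF-beta pathway were higher for 13 of 24 members, with a median of 1.38 (percentile 100, and 0.81 under median centring) and 0 lower. Among them were Il10 (5.29 ± 0.11, 39.1-fold), Tgfb3 (4.07 ± 0.18), the IL-1 receptor antagonist gene Il1rn (3.65 ± 0.14) and Etv3 (3.32 ± 0.01). Genes of inflammatory mediators were higher for 9 of 17 members, and 1, Casp1 (-1.16 ± 0.02), was lower. Il6 (4.98 ± 0.13), Il1b (3.50 ± 0.01), Il1a (3.29 ± 0.08) and the cyclooxygenase gene Ptgs2 (2.88 ± 0.08) were the highest of a list with a median of 1.57 at percentile 100. Without the filter on dim probes this median was 0.25, at percentile 94.5. Chemokine genes had a median of 4.32 (percentile 100), and 19 of 22 were higher, led by Ccl7, Cxcl1, Ccl8 and Ccl4, while Ccl6 was lower (-1.05 ± 0.03). Of the heat shock and immediate early genes 16 of 25 were higher in the same pool, as were most markers of fibroblasts, epithelium, B cells and T cells. Lists of some other cell types, such as neutrophils and platelets, had more lower than higher members. The values are given further on.

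Genes of complement were higher for 16 of 19 members and lower for 1, with a median of 3.50 (percentile 100). The C1 inhibitor gene Serping1 (5.74 ± 0.25), C1qb, C1s1 (5.00 ± 0.18) and C1qa (4.90 ± 0.02) were the highest, and C3 was lower (-1.06 ± 0.00). Scavenger receptors and genes of apoptotic cell uptake were higher for 16 of 27 members and lower for 2 (median 1.44, percentile 100, and 0.89 without members of other lists). The bridging ligand gene Gas6 (5.30 ± 0.12), the cholesterol exporter gene Abca1 (5.22 ± 0.20), Stab1 (4.39 ± 0.01) and Tgm2 (3.57 ± 0.06) were higher, and Dock2 (-1.23 ± 0.08) and Scarb1 (-1.20 ± 0.02) were lower. Of 42 lysosomal genes 17 were higher, among them Cd63 (4.68 ± 0.29), Acp5 (4.33 ± 0.09), Lgmn (3.94 ± 0.05) and Ctsl (3.24 ± 0.20), and 1 was lower, the regulator gene Tfeb (-1.35 ± 0.16). The lysosomal median was 0.83 (percentile 100), and 0.09 under median centring. Genes of iron and heme handling were higher for 11 of 20 and lower for 2 members (median 1.28, percentile 100, and 0.51 under median centring). Ceruloplasmin, Cp, read 4.42 ± 0.22 from 1 probe and 0.01 from another. Heme oxygenase 1, Hmox1, was higher at 3.65 ± 1.19, the hemoglobin scavenger receptor gene Cd163 at 2.85 ± 0.01 and the metal transporter gene Slc11a2 at 2.78 ± 0.10, while Hp and the siderophore-binding gene Lcn2 (-1.78 ± 0.04) were lower. Genes of matrix remodelling and growth factors were higher for 22 of 28 members and lower for 2 (median 3.58, percentile 100). Besides Adamdec1 and Mmp13, the growth factor genes Pdgfa (5.60 ± 0.05) and Igf1 (5.36 ± 0.16) were higher, whereas Mmp8 and the fibronectin gene Fn1 (-2.94 ± 0.28) were lower. Fibroblast and smooth muscle genes had a median of 4.40 in the same comparison.

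Lipid and cholesterol genes had a median of 0.31 (percentile 96.1), which was -0.28 under median centring and -0.05 without members of other lists. Of 28 members 9 were higher, among them Abca1, Apoe (3.65 ± 0.48), Cd36 and the cholesterol 25-hydroxylase gene Ch25h (3.13 ± 0.03), and 1 was lower, Apoc2 (-1.42 ± 0.10). Of 14 measured genes of retinoic acid metabolism 6 were higher and 2 lower (median 0.40, percentile 88.0, and 0.12 without the filter on dim probes). The retinaldehyde dehydrogenase genes Aldh1a1 (2.87 ± 0.25) and Aldh1a3 (2.66 ± 0.21) and the catabolic enzyme gene Cyp26b1 (2.12 ± 0.29) were higher. The retinoic acid receptor genes Rara (-1.85 ± 0.02) and Rarg (-1.51 ± 0.04) were lower. Of 23 purinergic genes 13 were higher and 1 lower (median 1.25, percentile 100, and 0.78 under median centring). The ectonucleotidase genes Entpd2 (4.86 ± 0.28) and Entpd1 (2.92 ± 0.02) and the receptor genes P2ry2 (2.76 ± 0.23) and P2ry14 (2.67 ± 0.13) were higher, and P2ry1 was lower (-1.85 ± 0.07).

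Chemokine receptor and adhesion genes went both ways, with 9 of 28 higher, 8 lower and a median of 0.31 (percentile 94.2), which was -0.17 under median centring. Vcam1, a ligand for integrins, had the highest value of this list (8.23 ± 0.33), above that of Adamdec1, but this probe was not well above background in the blood pool on every array, and its second probe read 5.04. Ccr7 (5.07 ± 0.14), Itgax and Ackr3 (3.29 ± 0.08) were also higher. Among the lower members were the monocyte chemokine receptor gene Ccr2 (-3.90 ± 0.18), the integrin gene Itgb7 (-2.89 ± 0.11) and Cxcr2 (-1.98 ± 0.05). Of 24 measured members of the list of Toll-like and other pattern-recognition receptors 4 were higher and 2 lower, with a median of 0.03 (percentile 47.7) that was below 0 under median centring, with the scanner software's ratios, without the second array and without the filter on dim probes. Tlr12 (5.00 ± 0.02), the lipopolysaccharide co-receptor gene Cd14 (2.80 ± 0.14), Tnfaip3 (1.91 ± 0.02), which encodes no receptor, and Tlr1 (1.28 ± 0.05, and 0.67 without a call under median centring) were higher, and Nod1 (-1.71 ± 0.02) and Tlr13 (-1.59 ± 0.17) were lower. Fc receptor and C-type lectin genes were higher for 10 of 24 members (median 0.61, percentile 99.9, and 0.16 under median centring), with Mrc1, Cd209f (5.53 ± 0.42), Clec4n (3.37 ± 0.16) and Mgl2 (2.43 ± 0.00) the highest and Clec4a3 lower (-1.70 ± 0.22). Genes of the type I interferon response had a median of -0.71 (percentile 0, and -1.42 under median centring), and 9 of 28 were lower. Irf7, a regulator of interferon production (-2.45 ± 0.05), Oasl2 (-2.34 ± 0.15), Usp18 (-2.30 ± 0.24) and Xaf1 (-1.87 ± 0.17) were lower, whereas 3 members were higher, Oasl1 (2.82 ± 0.11), Isg15 (2.31 ± 0.10) and Ifit1 (2.13 ± 0.02).

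Of 27 measured cell cycle genes 16 were higher and 0 lower (median 1.23, percentile 100, and 1.92 with the scanner software's ratios), among them the proliferation marker Mki67 (3.96 ± 0.03), Birc5 (3.36 ± 0.07), Cenpe (2.24 ± 0.15) and Prc1 (2.06 ± 0.06). Glycolytic genes had a median of -0.09 (percentile 18.3, and -0.75 under median centring), with 3 of 21 higher, Pfkfb3 (2.31 ± 0.05), Aldoc (1.61 ± 0.02) and Hk2 (1.51 ± 0.25), and Eno3 lower. Of 37 myeloid transcription factor genes 10 were higher and 1 lower, with a median of 0.54 (percentile 99.7) that was -0.04 under median centring. Spic (4.57 ± 0.14), the liver X receptor gene Nr1h3 (2.47 ± 0.12) and Nr4a3 (2.07 ± 0.08) were higher, and Klf13 was lower (-1.72 ± 0.02).

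**Figure D2:**
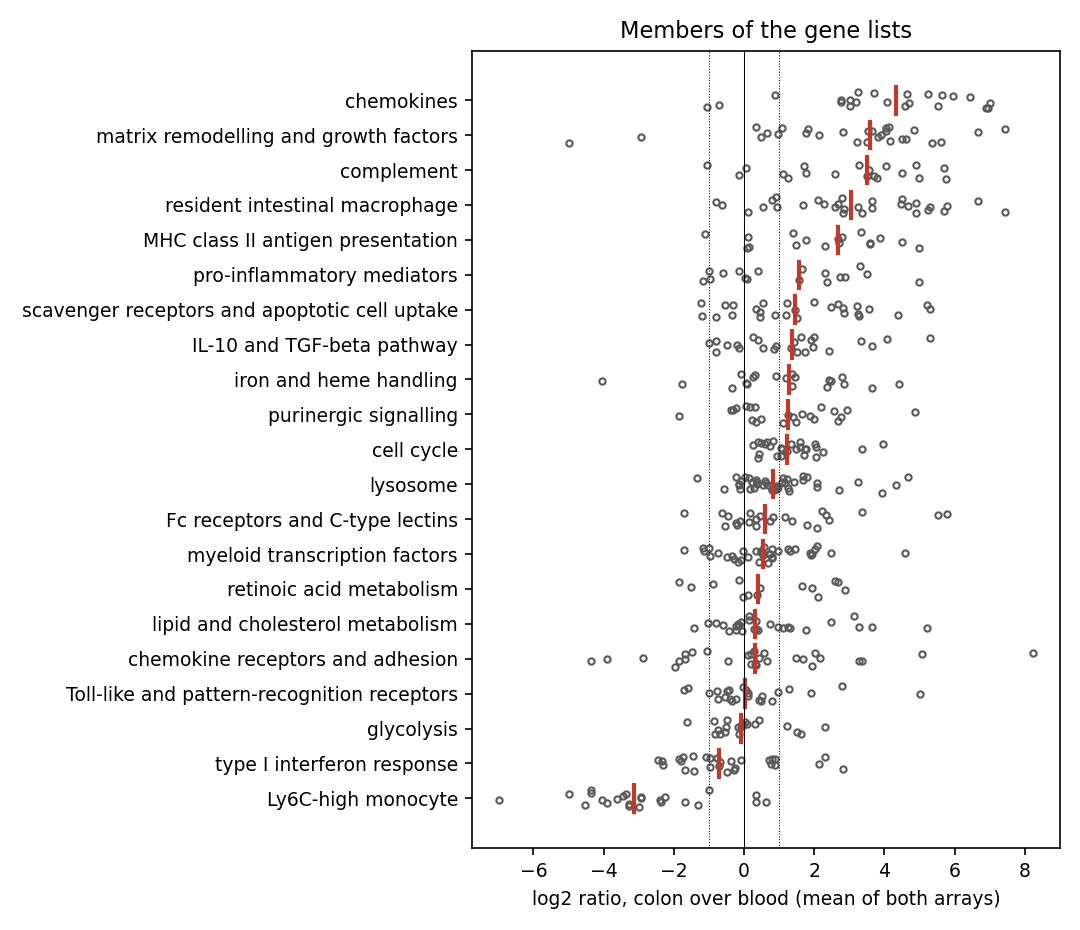
Log2 ratio of the colon pool over the blood pool (horizontal axis, mean of both arrays) for each measured member (circles) of 21 gene lists, ordered by their medians (red bars), with dotted lines at 2-fold. Medians run from -3.13 for Ly6C-high monocyte genes to 4.32 for chemokines.

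Markers of cell types outside the sort were read in the same way. Fibroblast and smooth muscle genes were higher in the colon pool for 15 of 16 members and lower for 0 (median 4.40, percentile 100), among them Dcn, Lum (6.82 ± 0.14, with a blood signal well above background on 1 array alone), Col1a1 and Col3a1. Epithelial genes were higher for 18 of 23 members and lower for 0 (median 1.71, percentile 100, and 3.79 with the scanner software's ratios), among them the keratin genes Krt8 (4.01 ± 0.24) and Krt19 (3.15 ± 0.07), Lgals4 (3.60 ± 0.03) and Agr2 (2.92 ± 0.13). B cell and plasma cell genes were higher for 11 of 14 members (median 1.76, percentile 100), led by the antibody joining chain gene Jchain (5.18 ± 0.22), Mzb1 (3.67 ± 0.20), Pou2af1 (2.85 ± 0.17) and Derl3 (2.60 ± 0.10). T cell genes were higher for 10 of 15 members (median 1.77, percentile 100), led by Il7r (4.10 ± 0.18), Cd28 (3.09 ± 0.22), Thy1 (2.87 ± 0.05) and Zap70 (2.67 ± 0.13). In the endothelial list 5 of 12 were higher (median 1.01, percentile 99.95, and 3.41 with the scanner software's ratios), among them Egfl7 (3.47 ± 0.19), Plvap (2.74 ± 0.08) and Ptprb (1.82 ± 0.01). Genes of plasmacytoid dendritic cells were higher for 4 of 9 (median 0.96, percentile 98.7), Ly6d (2.53 ± 0.12), Cox6a2 (1.90 ± 0.15), Klk1 (1.73 ± 0.11) and Spib (1.12 ± 0.06). Genes of NK and innate lymphoid cells were higher for 3 of 11 (median 0.61 at percentile 98.4, 0.14 at percentile 66.1 among genes well above background in both pools, and 1.73 with the scanner software's ratios), Il2rb (2.53 ± 0.03), Gzmb (2.16 ± 0.04) and Gata3 (1.41 ± 0.28). Mast cell and basophil genes were higher for 3 of 9 (median 0.52, percentile 97.9, with medians from 0.21 without the filter on dim probes to 2.25 with the scanner software's ratios, and percentile 92.3 among genes well above background in both pools), Kit (2.51 ± 0.12), Mcpt4 (2.12 ± 0.13) and Mcpt1 (1.45 ± 0.02). Conventional dendritic cell genes had a median of 0.13 (percentile 66.1), which was -0.19 among genes well above background in both pools, with Ccr7 higher and Flt3 lower (-1.505 ± 0.14) among 13 measured.

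Neutrophil genes were lower for 6 of 16 members and higher for 1, with a median of -0.30 (percentile 0.40). Among genes well above background in both pools this median was -0.0045, at percentile 47.0, and with the scanner software's ratios it was -1.21. Cxcr2, Stfa2l1 (-1.95 ± 0.12), Lcn2 and Ctsg (-1.53 ± 0.25) were lower, and the decoy receptor gene Il1r2 was higher (3.27 ± 0.15). Of 8 eosinophil genes 3 were lower, the ribonuclease genes Ear2 (-3.23 ± 0.07), Ear1 (-3.16 ± 0.24) and Ear10 (-3.03 ± 0.26), whose similar sequences may share signal. The eosinophil median was 0.09 (percentile 54.5) and was below 0 under median centring, with the scanner software's ratios and without the filter on dim probes. Platelet genes were lower for 5 of 12 members and higher for 1, with a median of -0.81 (percentile 0, and -2.74 with the scanner software's ratios). Treml1 (-2.21 ± 0.18), Itga2b (-1.62 ± 0.03) and Ppbp (-1.54 ± 0.10) were lower, and Pf4, a chemokine of platelets and of some macrophages, was higher (5.53 ± 0.30). None of 8 measured erythroid genes passed, at a median of -0.48 (percentile 0.47, and -1.15 under median centring), with Hba-a1 at -0.48 ± 0.18 and Hba-a2 at -0.30 ± 0.21. None of 5 measured genes of enteric glia and neurons passed either (median 0.41, percentile 82.9, and 0.023 under median centring), with Elavl4 at 0.50 ± 1.32.

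**Figure D3:**
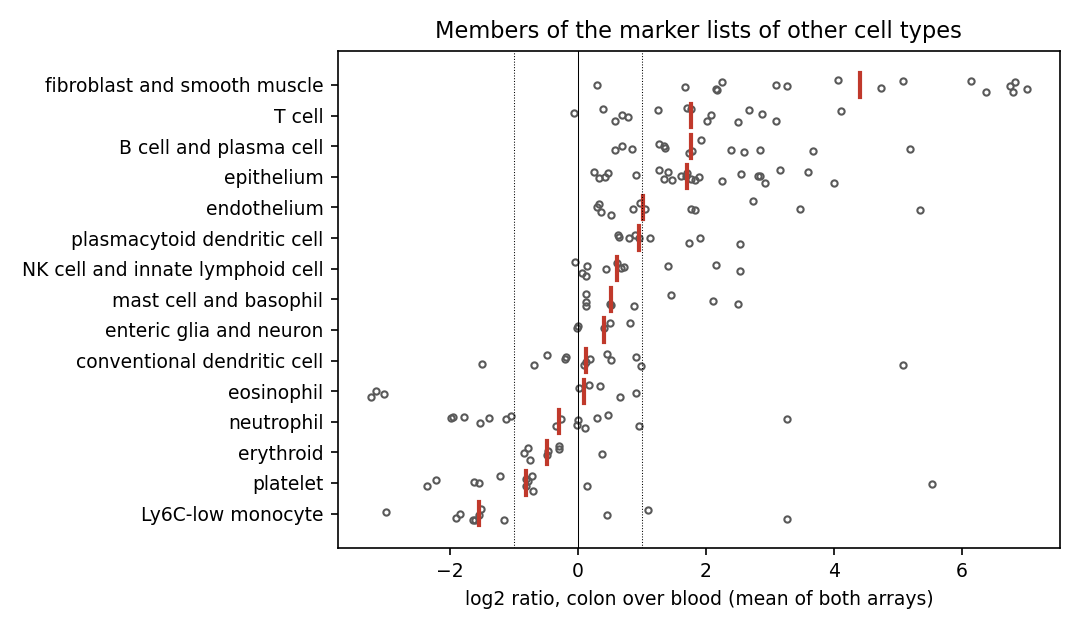
Log2 ratio of the colon pool over the blood pool (horizontal axis, mean of both arrays) for each measured member (circles) of 15 marker lists of other cell types, ordered by their medians (red bars), with dotted lines at 2-fold. Medians run from -1.55 for Ly6C-low monocyte genes to 4.40 for fibroblast and smooth muscle genes.

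Immediate early and heat shock genes, which respond to cell handling, were higher for 16 of 25 members and lower for 0 (median 1.65, percentile 100, and 0.84 under median centring). The highest were the chaperone genes Hspa1a (4.86 ± 0.20), Hsp90aa1 (3.69 ± 0.00) and Hspb1 (3.39 ± 0.02) and the stress gene Gadd45b (3.65 ± 0.11). Housekeeping genes had a median of 0.12 (percentile 59.5), which was -0.60 under median centring, and 2 of 16 passed, among them Tubb5 (1.26 ± 0.33). Of 3 measured sex-linked genes, Xist was higher (1.35 ± 0.05), and the median of 0.48 (percentile 81.2) was -0.12 under median centring and below 0 without the filter on dim probes.

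Where a gene was not well above background in 1 pool on both arrays, only a bound on the fold could be given. Of the higher genes 369 were of this kind, and of the lower genes 16. Each bound, here and below, refers to the mean of both arrays in the main setting. A single array or another setting can lie below it, as for Lyve1 at 5.11 on array 1 against a bound of 5.35 (log2). Where the dim signal exceeded the lowest signal counted as well above background, the bound equals the fitted fold. This was so for Lyve1, Fbln1, Plpp3, Svep1, Klrb1f, Cyp26b1, Klk1, Gata3, Kit, Mcpt1, Krt19 and Agr2, among others. The largest bounds in the colon pool were those of the matrix gene Postn (at least 43.1-fold higher), the hyaluronan receptor gene Lyve1 (at least 40.8-fold), Fbln1 (at least 37.7-fold), Plpp3 (at least 33.4-fold), the integrin gene Itga11 (at least 32.9-fold) and Svep1 (at least 29.4-fold). In the other direction they were those of Slfn4 (at least 6.38-fold lower in the colon pool), the platelet glycoprotein gene Gp9 (at least 5.00-fold), Cyp2ab1 (at least 3.84-fold), Klrb1f (at least 3.26-fold), AF067061 (at least 3.12-fold) and Scel (at least 2.73-fold). Among the marker genes above, the same limit held for Aldh1a3 (at least 6.23-fold higher), Cyp26b1 (at least 4.33-fold), Klk1 (at least 3.32-fold), Gata3 (at least 2.67-fold), Kit (at least 5.68-fold), Mcpt1 (at least 2.73-fold), Krt19 (at least 8.89-fold), Agr2 (at least 7.59-fold) and Ptprb (at least 3.52-fold). Besides Vcam1, Dab2 and Lum, the ratios of Il1a, Ackr3, C1s1, Cd163, Nr4a3, Derl3 and Il2rb rest on a blood signal, and those of Stfa2l1, Ctsg and Itga2b on a colon signal, that was well above background on 1 array alone. Under median centring 22 of the 177 named genes past the size rule lost their call, 16 of them while still at least 2-fold in the mean, because the arrays then differed and 1 fell short of the rule. The 5 lower genes among the 22 moved further from 0, namely Casp1 (-1.89 ± 1.44), Ccl6 (-1.87 ± 1.69), C3 (-1.89 ± 1.75), Dock2 (-1.88 ± 1.35) and Scarb1 (-1.92 ± 1.43). Higher genes still 2-fold in the mean were Hmox1 (2.84 ± 2.75), Cd14 (1.96 ± 1.60), Nr1h3 (1.79 ± 1.43), Mgl2 (1.62 ± 1.66), Pfkfb3 (1.62 ± 1.41), Ifit1 (1.58 ± 1.12), Isg15 (1.503 ± 1.75), Xist (1.15 ± 0.72), Aldoc (1.13 ± 1.03) and Tnfaip3 (1.11 ± 1.60), among others. Under 2-fold in the mean were Spib (0.90 ± 0.63), Hk2 (0.84 ± 1.59), Tlr1 (0.67 ± 1.18), Fabp4 (0.53 ± 1.17) and Tubb5 (0.49 ± 1.20), among others. With the scanner software's ratios Fabp4 (0.98 ± 0.03) and Tubb5 (1.17 ± 0.27) fell just short of the rule on 1 array, and with the mean over probes C3 did so too (-1.05 ± 0.08), whereas Dock2 was under 2-fold in the mean (-0.83 ± 0.08). The scanner software's ratios placed 34 named genes over 1.5 times further from 0, among them Cxcr2 (-3.76), Treml1 (-3.63), Cox6a2 (3.36), Mcpt4 (3.52), P2ry1 (-3.01), Ackr3 (5.54), Il1a (5.24), Cd163 (4.74) and Nr4a3 (4.22), and 0 of them nearer to 0. Probes of the same gene also differed in places. Another probe stayed under 2-fold for Igf1 (0.58), Slc11a2 (0.99), Birc5 (0.85), Ptprb (0.28), Dock2 (-0.43) and AF067061 (-0.72), besides Cp. The other Fbln1 probe read 2.36, against 5.24 for the probe that gave its bound.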

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

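A signal was seen in probes that entered no gene count. Among 2148 measured probes without a gene name, 264 passed the size rule, 217 as higher and 47 as lower in the colon pool. This group was not weighed further.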

How the results depend on the processing

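The alternatives were chosen before the data were examined, except the bounds in list medians and the probes without GT repeats, which were added after. The count of higher genes stayed within 1.5 times 2224 except under median centring without loess (1137), a 1.5-fold (3493) and a 4-fold threshold (954). The count of lower genes stayed within 1.5 times 699 except with the scanner software's ratios and the identical deposited value table (2081 each), a 1.5-fold (1725) and a 4-fold threshold (130). Thresholds change counts by construction, and for the scalings the cause was not tested. With 1 array alone, 2398 to 2641 genes were higher and 847 to 859 lower. Without the filter on dim probes the counts were identical, since 0 of the 11560 genes outside it were at least 2-fold in the same direction on both arrays, so this setting tests nothing about them. The correlation of both arrays was 0.804 under median centring, where 2900 genes had a dye component of at least 1 against 39 in the main setting, and 0.952 without the filter. Member counts of the resident macrophage, Ly6C-high monocyte and MHC class II lists stayed within 1.5 times under every alternative run on them. Among the 177 named genes past the size rule, 0 of 1593 values changed sign and 650 moved by more than the SD between arrays. The 0 was partly fixed in advance. A called gene cannot change sign on either array alone, Aquantile scaling leaves ratios as they are, and the deposited value table repeats the software's ratios. Under median centring 22 of the 177 genes lost their call, 16 of them still at least 2-fold in the mean of arrays that then differed. There 1128 of the 2224 higher and 532 of the 699 lower genes kept theirs. The medians of 7 lists changed sign under median centring, of 2 with the scanner software's ratios, of 3 without the filter on dim probes, and of 1 each among genes well above background in both pools, without the second array and without members of other lists. Of these lists, that of myeloid transcription factors (-0.044 under median centring) had a main median beyond the limits of the random lists, and the cause was not tested. Of 585 list percentiles 15 moved across the lower or the upper limit named in the methods. With bounds in place of fitted ratios, the median was 3.55 for matrix genes and -0.77 for platelet genes. Signals near the local background limit dim genes, whose ratios the offset compresses.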

Other observations

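The lists here were chosen after the data had been seen. In the list of pancreatic enzymes, 12 of 13 measured genes were higher in the colon pool and 0 lower (median 2.68, percentile 100), among them the amylase gene Amy2a5 (6.27 ± 0.15), the carboxypeptidase gene Cpb1 (4.01 ± 0.28, at least 16.1-fold), the chymotrypsinogen gene Ctrb1 (3.02 ± 0.12) and the lipase gene Pnlip (2.97 ± 0.13, at least 7.82-fold). Members of all 4 enzyme families in the list passed, namely amylases, lipases, carboxypeptidases and serine proteases. Of 4 measured interferon genes 2 were higher, Ifnb1 (7.19 ± 0.37) and Ifng (1.35 ± 0.32, at least 2.54-fold), while the alpha gene Ifna1 was at -0.17 ± 0.08 (median 0.61, percentile 95.3). Interferon response genes had a median of -0.71 in the same comparison.

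Of 12 measured members of a list of neural guidance and adrenergic signals, 3 were higher. They were Nrp2 (3.73 ± 0.11), Sema3c (3.02 ± 0.15, at least 8.10-fold) and Gdf15 (5.64 ± 0.11), a cytokine gene that is of neither class. The median of this list was 0.50 (percentile 94.6), and 0.48 with genes at their bound. Of 16 Notch and Wnt genes 5 were higher, among them Jag2 (1.79 ± 0.11, with a blood signal well above background on 1 array alone) and Wnt5a (1.19 ± 0.04, at least 2.26-fold), with a median of 0.60 (percentile 99.7). Proteasome subunits had a median of -0.27 (percentile 3.36) with 1 of 14 lower, Psma7 (-1.21 ± 0.27). Of 79 ribosomal protein genes 0 passed (median -0.03, percentile 1.03).

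Among the tests below, that of the immediate early genes was set after its result was seen, and the others before, although the spread used for the third pattern was added after its values were seen. The first pattern is that markers of fibroblasts, epithelium, T cells, B cells and pancreatic acinar cells were higher in the colon pool. If RNA of such cells entered the pool despite the CD11b, CD11c and CX3CR1 gate, marker genes not looked at before should be higher too, a test that replaced the share of the first lists themselves (93.8% of fibroblast genes, for example), which was circular. The size rule was passed as higher by 100% of a second fibroblast list (10 of 10), 75% of a second epithelial list (6 of 8), 88.9% of a second B cell list (8 of 9) and 61.5% of a second acinar list (8 of 13), and by 42.9% of a second T cell list (3 of 7), which decides nothing. For the first 4, RNA of other cells in the pool is a candidate source, and the levels of abundant transcripts, Col1a1 (6.79 ± 0.04), Krt8 (4.01 ± 0.24), Jchain (5.18 ± 0.22) and Amy2a5 (6.27 ± 0.15), add no test, since these genes belong to the lists that made the pattern. Expression by the sorted cells themselves was not tested and stays open, and of the fixed markers 12 of 16 fibroblast, 9 of 23 epithelial, 12 of 15 T cell and 9 of 14 B cell genes were well above background in the blood pool as well.

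The second pattern is that heat shock and immediate early genes were higher in the colon pool. The 6 heat shock members were all higher (median 3.34), as were 57.9% of a second chaperone list (11 of 19, median 1.49, percentile 100), 0 of which were lower. A heat shock response in the colon cells may account for these genes, and tissue, digestion and cell type cannot be separated by this design. RNA of other cells, as in the first pattern, was not separated from such a response either. The highest member of the second list past the size rule was Serpinh1 (5.25), with a blood signal well above background on 1 array alone. Hspb8 (3.05) was not well above background in the blood pool on either array. A handling response shared by all immediate early genes stays open. Their median was 1.34 and 10 of 19 were higher, Egr2 (3.34 ± 0.04) and Ier3 (3.15 ± 0.30) among them, while 4 lay below 0 by more than their SD, which is technical alone, Fos (-0.40 ± 0.27), Ier2 (-0.59 ± 0.07), Dusp1 (-0.55 ± 0.16) and Atf3 (-0.18 ± 0.10), so the criterion first written was met and a stricter one, set once these values were known, was not.

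The third pattern is that 76.1% of the calls were higher in the colon pool. A stronger signal for dim genes of the colon pool was weighed after loess alone. In the top tercile of genes by intensity, 64.7% ± 2.39 (SD over arrays) of the calls were higher (685 higher, 373 lower). This lay above the bound of 60% set beforehand, so in that setting the excess was not confined to dim genes. The share in this tercile is not given under another scaling, so whether dim signal is the whole cause stays open. Loess normalization stays open, since the share of higher calls among all calls was 67.1% under median centring and 60.4% ± 1.27 with the scanner software's ratios, where calls rose in both directions (3175 higher, 2081 lower), so that the lower share does not show that loess made the higher calls. For genes of further cell types present in the colon pool alone, 16.6% of higher calls were not well above background in the blood pool. For lower calls in the colon pool this was 2.29%, a difference of 14.3 points ± 0.790. Genes that the sorted colon cells express and monocytes do not would give the same reading. More of the higher calls were also large, with 448 against 31 at least 8-fold on both arrays. The difference therefore cannot tell whether further cell types contribute. A difference between the cell types themselves was not tested.

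A set of very bright probes differed between the dye orientations. The 101 measured probes with at least 6 GT units in a row had a median dye component of 0.89 (interquartile range 0.80 to 1.06) against 0.00 for the other 22101, and a median log2 intensity of 14.95 against 8.36. Their median ratio was 1.60 on array 1 and -0.25 on array 2. Of 39 genes with a dye component of at least 1, 37 were read from such a probe. None of the called genes was read from one, and without these probes 2228 genes were higher and 701 lower.

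Along transcripts, probes of 1688 RefSeq transcripts with positions at least 500 bases apart gave a median ratio of the upstream probe minus that of the downstream probe of 0.09 on array 1 and 0.18 on array 2.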
